A study of Rattus norvegicus with 4 samples.

How the data were processed

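RNA abundance was measured by 3' end sequencing in 4 separate preparations of untreated FRT cells, which form the only group of the series. Per the labels' protocols, total RNA was column-purified, libraries were made with a QuantSeq 3' mRNA kit, and single-end reads of 100 bases were sequenced. In this library type a transcript yields a tag near its 3' end, so counts were not divided by gene length. Reads were aligned with STAR and counted with HTSeq on the rat build rn6, per the submitters' processing notes. Versions, the annotation release, the strand setting and the use of molecular identifiers are not given in the sources used here.

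The authors deposited raw counts per gene, whole numbers for 32754 versioned Ensembl gene IDs in each library, followed by 5 summary lines of the counter. Those lines were left out of library totals and of the tests on genes. They entered only comparisons of whole libraries and the total of all uniquely aligned reads, used in a check on the most abundant gene. They record uniquely aligned reads assigned to no gene (35.8% ± 1.76 of uniquely aligned reads, SD, n = 4). They also record reads overlapping more than 1 gene (0.0418% ± 0.00846, SD, n = 4) and alignments set aside as not unique. Genes that share sequence with close copies therefore lose counts, and copies of a gene family are undercounted to an unknown extent. The deposited counts carry no mark of amplified duplicates, so intervals and floors cover counting error only.

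The files do not pair the IDs with gene symbols, biotypes or positions. In the RefSeq gene table used here, of the rat assembly GRCr8, the column for Ensembl IDs was empty, so none of the 32754 IDs was linked to a symbol. The 29 gene lists and the gene pairs fixed before the data were examined were therefore not analysed here, and neither were the planned tests, backgrounds and scalings that need them. The rule for named genes, fixed at the same time, asked for the 20 genes with the highest mean CPM, members of the lists, and the 10 genes with the highest edgeR tagwise dispersion among those at 10 CPM or more that varied beyond counting noise. Without symbols, IDs are printed only for the first 2 genes by abundance and the first 2 by dispersion. The others are described by rank.

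Levels are given as CPM, the counts of each library divided by its total over genes and scaled to a common total. A gene was called detected at 1 CPM or more in every library. Totals ran from 1160202 to 1999175 counts, so 1 count was worth 0.500 to 0.862 CPM, and a count of 0 allows up to 3 counts, or 1.50 to 2.59 CPM. Shares of counts carry exact Clopper-Pearson 95% intervals. The expected number of genes with a count at lower depth was computed from the hypergeometric distribution.

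Variation between preparations was tested for genes with at least 40 counts in all, by a chi-square test on 3 degrees of freedom of each gene's counts against those expected from edgeR's TMM effective library sizes, with Benjamini-Hochberg adjustment at 0.05. The most abundant genes were also tested by 100000 multinomial draws, whose smallest possible p is 1e-05. The common biological coefficient of variation (BCV) was estimated with edgeR after its filter on low counts, with an intercept-only design. A test of whether a gene varied more than genes of similar abundance compared its quasi-likelihood dispersion with edgeR's robust trend, and was chosen after seeing the data. Fold ranges are the highest over the lowest library after TMM scaling.

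The scripts were tested on simulated data. With counting noise alone, 0 of 7571 genes were called. With 200 genes changed in 1 library, 78 of 100 genes changed 2-fold and 98 of 100 genes changed 4-fold were recovered, and 13 of 7371 unchanged genes were called. Simulated BCVs of 0.1, 0.3 and 0.5 were estimated as 0.0982, 0.292 and 0.47, each below the value set. The trend test recovered 189 of 200 genes changed 8-fold against a background BCV of 0.3, among 6456 genes, and called 0 genes when none was changed. Every simulated gene had that same BCV, so this does not give the recovery in the deposited counts, where the spread differs between genes. R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.

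Alternatives tried were other detection thresholds, other scalings (deposited totals, TMM, DESeq2 size factors, totals without the 20 most abundant genes), other count minimums, libraries thinned to the smallest total, and leaving out each library in turn. The last scaling and a chi-square divided by its inflation in low-count genes were added after seeing the data.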

Results

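FRT is an epithelial cell line derived from the thyroid of the Fischer rat. It grows as a polarised monolayer and is widely used as a host for expressing ion channels. The series profiled the RNA of this line in the untreated state, in 4 separate preparations, with no second condition. The comparisons it allows are therefore between genes within the line and between the preparations. Genes are known here by Ensembl ID only, so that abundance classes and genes that moved together are described in place of pathways. The 4 libraries held 1304869, 1999175, 1670508 and 1160202 counts assigned to genes in replicates 1 to 4.

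The first question was which part of the annotated gene set the line expressed. Of 32754 annotated genes, 8731 reached 1 CPM in every library, or 26.7% of the annotation, and these genes held 99.5% of all gene counts. Their median level was 26.0 CPM. No count was found for 19384 genes in any library, and 13370 genes had a count in at least 1 library. A level of 10 CPM in every library was reached by 5463 genes, 100 CPM by 1023 genes, 1000 CPM by 31 genes and 10000 CPM by 3 genes.

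Detection was similar from preparation to preparation. Each library held 10163 ± 222 genes at 1 CPM or more (SD, n = 4), and 74.0% of the genes that reached this level in any library reached it in all 4. At these depths 1 CPM means at least 2 counts. In at least 1 library, 11797 genes reached 1 CPM, a number that includes the 8731 detected genes. The rest of them reached it in part of the libraries only. Genes with no count are not shown to be absent. Taking 25% of the counts would have given an expected 9289 to 9854 genes with a count per library, 50% would have given 10126 to 10734, and the full libraries gave 10803 to 11507. The number of genes was thus still rising slowly with depth.

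A very small group of genes held much of the RNA counted. The most abundant gene, ENSRNOG00000043866.1, stood at 218727 CPM ± 73355 (SD, n = 4), and ENSRNOG00000030478.3, the second, at 53994 CPM ± 11235 (SD, n = 4). The third gene had a mean of 48584 CPM ± 14575 (SD, n = 4), after which levels dropped to 11024 CPM for the fourth. The 3 genes together took 32.1% ± 8.19 of gene counts, and the 20 most abundant genes took 40.4% ± 7.25 (SD, n = 4). The genes of ranks 4 to 20 lay between 11024 and 1960 CPM.

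How far a library was dominated by these genes differed between preparations. The most abundant gene took 20.8% of counts in replicate 1 (95% Clopper-Pearson interval 20.8 to 20.9) and 31.9% in replicate 2 (31.9 to 32.0). It took 20.4% in replicate 3 (20.3 to 20.5) and 14.3% in replicate 4 (14.3 to 14.4). The highest share was 2.23 times the lowest, a difference far outside the counting intervals. In replicate 2, 35 genes made up 50% of the counts, compared with 123 in replicate 1, 67 in replicate 3 and 234 in replicate 4. TMM scaling factors, which offset such dominance, ran from 0.889 in replicate 2 to 1.14 in replicate 4.

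**Figure D1:**
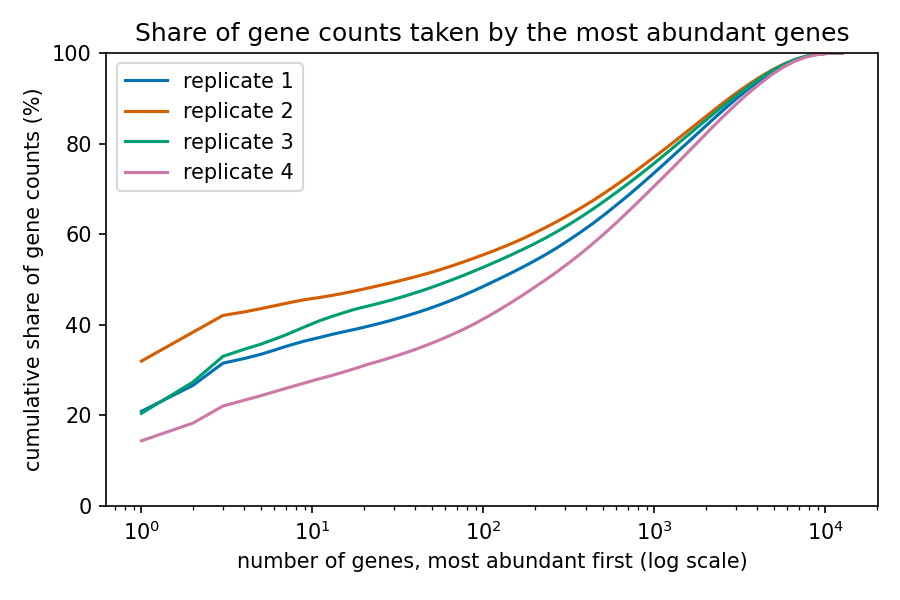
Cumulative share of gene counts (y axis, percent) against the number of genes, ordered from the most abundant in each library (x axis, log scale), with 1 line per replicate. The lines start at 14.3% in replicate 4 and 31.9% in replicate 2, and all approach 100% near 10000 genes.

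The next question was whether the preparations differed by more than counting noise. They did for most genes that could be tested: 4973 of 7571 genes, or 65.7%, varied between the 4 libraries at an adjusted p under 0.05 (chi-square test on counts, Benjamini-Hochberg), compared with 0 genes when the same totals were redrawn with counting noise alone. Of the 5072 tested genes at a mean of 20 CPM or more, 1858 differed at least 2-fold between their highest and lowest library, and 251 differed at least 4-fold. Counting noise alone gave 22 and 0 such genes. With the chi-square divided by 3.63, its inflation in genes with 40 to under 100 counts, 1149 of the 7571 genes (15.2%) were called. This setting was chosen after seeing the data. That most genes varied thus holds against counting noise alone. The test measures whether these libraries differ. It cannot separate differences between cultures from differences that arose in library preparation.

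Measured by the chi-square, the excess over counting noise was larger in classes of genes with more counts. Among genes with 40 to under 100 counts in all, 1012 of 2053 were called, and the median chi-square was 3.63 times its value under counting noise. Among genes with 1000 to under 4000 counts, 660 of 713 were called, and the median was 19.9 times that value. Of the 121 genes with 4000 counts or more, 120 were called, with a median chi-square of 140 times that value. The size of the differences did not grow in the same way. The median fold range was 2.72 in the lowest of the 5 classes (1.67 in the simulated counts), 1.94 (1.34), 1.63 (1.18) and 1.59 (1.10) in the next 3, and 1.91 (1.05) in the highest. All 20 of the most abundant genes were called. For ENSRNOG00000043866.1 and ENSRNOG00000030478.3 no multinomial draw reached the observed chi-square (exact multinomial test by Monte Carlo draws, p = 1e-05, the smallest that the draws can give). Fold ranges of the 20 genes ran from 1.13 to 4.23.

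**Figure D2:**
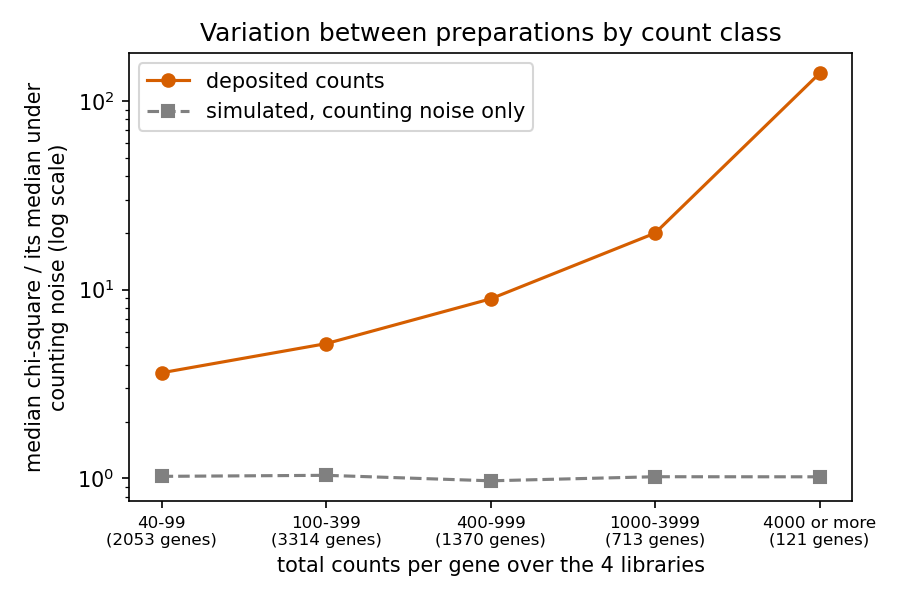
Median chi-square of variation between the 4 libraries, divided by its median under counting noise (y axis, log scale), for genes grouped by their total counts (x axis). Circles are the deposited counts, rising from 3.63 to 140, and squares are counts simulated with counting noise only, which stay between 0.971 and 1.04.

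Over the 6186 genes that passed edgeR's filter, the common BCV was 0.291, a spread of 29.1% between preparations beyond counting noise. Pairs of libraries differed in how close they were. Replicates 1 and 3 were the closest pair, with a BCV of 0.222 and a Pearson correlation of 0.935 of log2(CPM + 0.5) across genes, while replicates 2 and 3 were the most distant, with a BCV of 0.334 and a correlation of 0.886. Genes are not independent replicates, so these correlations only describe the libraries. As a check for a library deposited more than once, the counts of each pair were tested against counting error only. Between 1607 and 2907 genes were called in each of the 6 pairs, and all 4 libraries were kept as separate samples.

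The genes of highest dispersion showed changes of an order of magnitude. ENSRNOG00000007319.7 was measured at 1077 CPM in replicate 1 and 1197 CPM in replicate 3, against 109 CPM in replicate 2 and 79.3 CPM in replicate 4, a fold range of 18.1. ENSRNOG00000052293.1 stood at 120 CPM in replicate 2 and at 12.1 to 25.7 CPM in the other libraries, a fold range of 12.7. Its mean of 42.7 CPM ± 51.9 (SD, n = 4) was set by replicate 2 and was 16.9 CPM without it. Both genes were chosen from among those that had passed the test against counting noise, so that test is no further evidence for them. Across the 10 genes of highest dispersion, fold ranges ran from 8.63 to 19.9.

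Set against genes of similar abundance rather than against counting noise, few genes stood out. Of 6186 genes, 4 varied more than edgeR's robust trend at an adjusted p under 0.05 (360 at an unadjusted p under 0.05), and all 4 were among the 10 genes of highest dispersion. Both measures come from the same counts, so this overlap is no separate evidence. The trend and the spread of genes around it were fitted to these same genes. A low number past it therefore does not show that the other genes varied little. ENSRNOG00000007319.7 was past the threshold, with an edgeR adjusted p of 0.0397, and ENSRNOG00000052293.1 missed it, with an edgeR adjusted p of 0.0521. The values of both lie close to the threshold. All 10 genes of highest dispersion had fold ranges of 8.63 or more, and only 4 passed. A gene that missed the threshold may therefore still have differed widely between libraries.

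**Figure D3:**
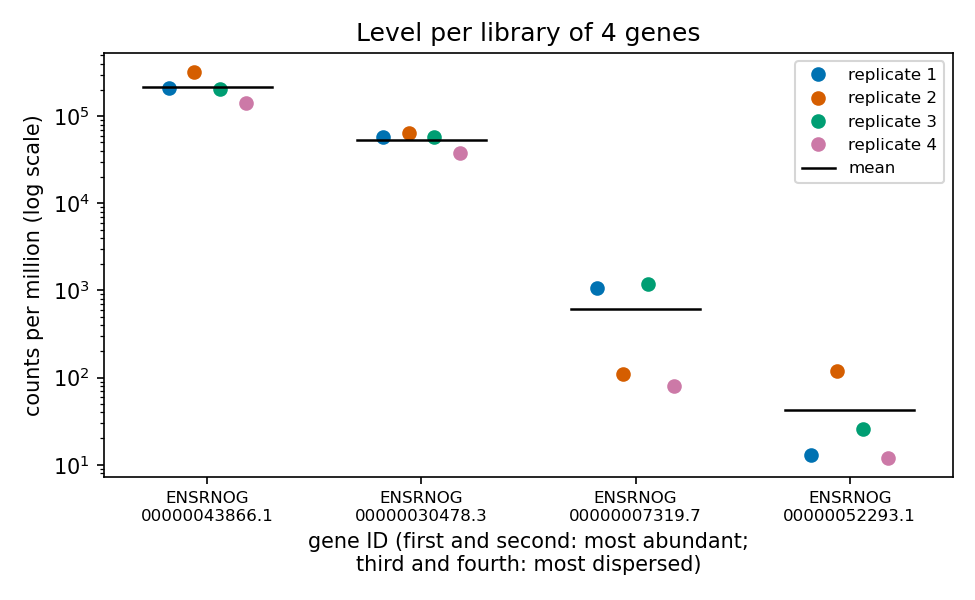
Level in CPM (y axis, log scale) in each of the 4 libraries (coloured points) and their mean (black line) for the 2 most abundant genes and the 2 genes of highest dispersion (x axis, Ensembl IDs). The most abundant gene lies between 143304 and 319358 CPM, whereas the first of the dispersed genes splits into 2 libraries above 1000 CPM and 2 libraries at 109 and 79.3 CPM.

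The 20 most abundant genes did not all move the same way between preparations. After TMM scaling, the genes of ranks 1, 2 and 19 were highest in replicate 2 and lowest in replicate 4, and the gene of rank 3 was highest in replicate 3 and lowest in replicate 4. Of the 17 genes of ranks 4 to 20, a range set after seeing the values and not tested, 14 were highest in replicate 3 and 12 were lowest in replicate 2 with the same scaling. With the 3 other scalings these counts were 13 and 12 or 13. Over all 3736 called genes at 20 CPM or more, 24.5% were highest in replicate 3 and 28.3% (1059 genes) were lowest in replicate 2 with TMM. With deposited totals 1448 of these genes were lowest in replicate 2, so this baseline depends on the scaling. In these genes, after TMM scaling, the 3 principal components that 4 centred libraries allow held 48.5%, 36.6% and 14.9% of the variance between libraries, where equal components would hold 33.3% each. On the first, replicate 3 at 0.71 and replicate 1 at 0.22 lay opposite replicate 2 at -0.53 and replicate 4 at -0.40. The second separated replicate 4, at 0.76, from replicate 2, at -0.55.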

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

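Of the tests in this part, the comparison of count classes was chosen only after its result was seen. The chi-square divided by its inflation in low-count genes was also added after seeing the data. The others were set out before their results were seen.

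Each of 13 sets of 4 values, 1 value per library, was examined for a library standing apart from the rest, and 2 sets passed Dixon's 95% critical value, where chance passes about 1 set in 20. The share of uniquely aligned reads that overlapped more than 1 gene was 0.0544% in replicate 4 and 0.0362% to 0.0385% in the other libraries, a gap of 0.873 of the whole range. The level of ENSRNOG00000052293.1 was 120 CPM in replicate 2 and 12.1 to 25.7 CPM elsewhere, also a gap of 0.873 of the range. This gene was printed for its high dispersion, which a single high library gives, so the chance rate above does not apply to it. Over the 3736 called genes at 20 CPM or more, 187 genes (5.01%) had such a library, close to the share that chance gives.

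Much of the sequence data lies outside the gene counts. The files record 1.70 alignments set aside as not unique for each uniquely aligned read, from 1.502 in replicate 3 to 2.117 in replicate 1. Whether these are alignments or reads is not given in the sources used here. A further 35.8% of uniquely aligned reads were assigned to no gene, from 34.4% in replicate 2 to 38.3% in replicate 1. Whether such reads lie within annotated genes cannot be told, since the strand setting is not given. The reads assigned to no gene numbered 645244 to 1049460 per library, where a count of 0 would allow up to 3. Neither set of reads entered the gene comparisons. Reads assigned to no gene were, however, part of the total in a check on the most abundant gene, given below.

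The first pattern weighed was that most tested genes varied between preparations beyond counting noise. Amplified copies of the same molecules would multiply the counting variance of every gene by about the same factor. The median chi-square was 5.49 times as large in genes with 1000 to under 4000 counts as in genes with 40 to under 100 counts. That argues against copies as the whole cause of the excess in genes with many counts. With the chi-square divided by 3.63, its inflation in the low-count genes, 1149 of 7571 genes were called. Copies are thus not excluded as the reason why most genes were called. Scaling by totals that a few genes dominate is argued against too, because TMM scaling called 0.953 times as many genes as deposited totals did. A GC or length bias that differs between libraries was not tested, since the IDs were not linked to sequences. Differences between the cultures themselves, such as density or passage, stay open and untested, since the labels give no such record.

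The second pattern was that the most abundant gene took a different share of counts in each library. A varying share of reads assigned to no gene does not account for it. The share of uniquely aligned reads assigned to genes ran only from 61.6% to 65.6%, a ratio of 1.06. Among all uniquely aligned reads, the highest share of the most abundant gene was still 2.27 times the lowest. That small range fixed this result in advance, so it adds nothing further. Unequal loss of reads from its sequence copies among the alignments set aside, and a true difference between preparations, stay open, and no biological explanation was tested.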

How the results depend on the processing

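No paired analysis was possible because the series has 1 group. The number of detected genes, 8731, ranged from 6299 (10 or more counts in every library) to 11797 (1 CPM in at least 1 library), and from 8868 to 9052 when a library was left out. TMM and DESeq2 scaling gave the same number by construction, since 1 CPM meant at least 2 counts in each library under either. The 4973 genes varying between preparations became 5218 with deposited totals and 4974 with DESeq2 size factors, with 4575 and 4943 genes called in both. Leaving out a library gave 3486 to 4220 genes. The number moved by more than 1.5 times under 3 settings. With a minimum of 400 counts it was 1877, because only 2204 genes were tested. With the chi-square divided by 3.63, its inflation in genes with 40 to under 100 counts, it was 1149. Against the edgeR trend of genes of similar abundance it was 4 of 6186 genes tested. That setting changes the null, the test and the filter together. The last 2 settings were chosen after seeing the data. The common BCV of 0.291 rose to 0.355 without the filter on low counts (the cause was not tested), was 0.310 with deposited totals, and ran from 0.278 to 0.316 when a library was left out. The mean share of the most abundant gene, 21.9%, ran from 18.5% without replicate 2 to 24.4% without replicate 4. All 4 printed genes stayed past the threshold for variation beyond counting noise under every alternative in which they were tested, apart from the trend of similar genes, which only ENSRNOG00000007319.7 passed. Depth limits what can be said below 1.501 to 2.586 CPM, the level of 3 counts in the deepest and the shallowest library.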

Other observations

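The prediction of each test in this part was written before its result was seen, but after the libraries had been compared, and the scaling used in the second test was itself chosen after seeing the data.

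Genes were compared by the library in which each was highest and lowest. Among the 3736 called genes at 20 CPM or more, the commonest of the 12 possible pairs was highest in replicate 3 and lowest in replicate 2, with 505 genes (13.5%), against 8.33% if all pairs were equally frequent. The least common was highest in replicate 3 and lowest in replicate 1, with 135 genes (3.61%). Of the 10 genes of highest dispersion, 4 were highest in replicate 4 and lowest in replicate 3, and 2 had the opposite order. Replicate 1 was highest for 19.2% of genes and lowest for 17.9%, below the 25% of an equal share in both directions, so it lay closest to the middle of the 4 preparations.

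A hypothesis for this uneven frequency of the pairs is that it follows sequencing depth. Only 7.71% of these genes were ordered by library depth, upwards or downwards, against 8.33% by chance. That argues against depth as the order of all 4 libraries. The deepest library, replicate 2, was highest and the shallowest, replicate 4, lowest in 428 genes (11.5%). The reverse held in 358 genes (9.58%), and each share lay above the 8.33% of equal pairs. A part of the differences that follows depth therefore stays open. A second is that it may come from the few genes that take most of the counts. With totals that leave out the 20 most abundant genes, 13.5% of genes had the pair that was commonest with TMM. This test decides nothing, because the share set beforehand for excluding the explanation lay above the starting value and because those totals scale the libraries much as TMM does. The explanation stays open. With deposited totals, the order highest in replicate 4 and lowest in replicate 3 held 597 genes and the former pair 425. The former pair held more genes than that order with DESeq2 size factors (500 against 387) and with totals without the 20 most abundant genes (504 against 351). Its lead thus depends on the scaling.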
